A study of Mus musculus with 12 samples.

How the data were processed

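The samples were 12 Affymetrix expression arrays of mouse mammary gland RNA, 3 arrays in each of 4 groups. Per the labels, each array held RNA from a pool of 3 mice, extracted with a kit for lipid-rich tissue and labelled with biotin as cRNA. The values used were 1 deposited table of 45101 probe sets by 12 arrays. Its values lay on a log2 scale, judged from their range, since the labels do not give the scale or its base. The authors had normalized the deposited log2 values between arrays, as judged from percentiles that nearly coincide, and genes were not centred. The submitters' processing notes name MAS5 with no role or version. MAS5 itself gives linear signals, so the deposited log2 table was either log-transformed or made by another method. Summarization, background correction and normalization are not given in the sources used here. The array medians lay between 5.84 and 5.91. No scanner files were used here, and the number of arrays limits the precision.

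Probe sets were named from the platform annotation given with the table, whose symbols were looked up through the Entrez ID in a RefSeq gene table of assembly GRCm38.p6; 0 symbols changed. Of 45037 probe sets that are not controls, 34945 had 1 symbol, 932 had several and 9160 had none. Only probe sets with 1 symbol were named. The RefSeq table was also used to find which genes lie near each other, and none of its coordinates is given.

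Groups were taken from the labels. Probe sets were tested if they lay above the array median on at least 3 of the 12 arrays, which kept 23709 probe sets and, with 1 probe set per gene, 12004 genes. A gene was represented by its probe set with the highest mean log2 value over the 12 arrays. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trended prior) on 4 group means over all 12 arrays, with 8 residual degrees of freedom and no replicate block. Contrasts were wild type minus null at 8 h and at 24 h, the difference of these differences (24 h minus 8 h), and 24 h minus 8 h within each genotype. A probe set was called at a Benjamini-Hochberg adjusted p below 0.05 over the probe sets tested. SE is the moderated standard error on the log2 scale. The labels number the pools 1 to 3 in each group and do not say that a number marks a shared batch, litter or day. In the data, the deviations from the group means of same-numbered null arrays at 8 h and 24 h correlated in all 3 pairs (r from 0.26 to 0.52, each over 0.1), so the numbers were taken to pair the samples for time in null glands, and values with a replicate block are given where they differ. The limma p-values of probe sets measure the spread between pools, which the labels call biological replicates.

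Of 31 gene lists fixed before the data were examined, 30 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with the correlation estimated per list as an alternative. The list p-values were adjusted over the lists of 1 comparison. With the preset correlation 3 lists passed for genotype at 8 h, 14 for genotype at 24 h, 10 for the interaction, 15 for time in wild type and 12 for time in null glands, and with an estimated one 0 in each, so not all are described.

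Genes were named by a rule fixed before the data were examined. It took Pgr, every tested member of the list of mammary progesterone targets, and in each genotype comparison the 10 largest rises and 10 largest falls among representing probe sets that were called, whose groups did not overlap and whose higher group mean lay above the mean of the array medians. It took the 5 largest in each direction for the interaction, without the rule on overlap, and for each time comparison. For each list described it took up to 4 called members with the largest change. For 3 arrays against 3, chance alone gives groups that do not overlap for 10% of genes.

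The calculation was tested on simulated data with the real means, the moderated spreads and 200 changed probe sets among 23709. Values were drawn independently, without the correlation between genes or arrays of the real data, so the shares recovered do not cover it. For the genotype comparison at 8 h, 89.6% of the probe sets changed 2-fold were recovered. For the interaction, 68.7% of those changed 2-fold and 11.9% of those changed 1.5-fold were recovered. Alternatives covered the filter, the variance prior, a floor on low values, quantile normalization, centring, array weights, the arrays in the fit, a replicate block, 1 probe set per gene, a fold threshold and leaving out each array. The lists were rerun under the same alternatives, except the robust prior and the fold threshold, which camera does not take. Figures were drawn with matplotlib 3.10.9.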

Results

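Mammary gland gene expression was measured in ovariectomized BALB/c mice, 10 weeks old, that were wild type or lacked the progesterone receptor (null, from here on). All mice received 17β-estradiol (100 ng) for 24 h and then 17β-estradiol with progesterone (2.5 ug) for 8 or 24 h. The length of 17β-estradiol treatment thus differed between the times as well, and the clock hour of collection may differ. A change over time therefore cannot be assigned to progesterone alone. Each of the 4 groups had 3 arrays, and each array held a pool of 3 mice. Correlations within groups ranged from 0.965 to 0.993 over the tested probe sets. All groups received progesterone, so dependence on the receptor was read from the difference between genotypes. Without a group given no progesterone, an acute response to it cannot be told apart from a lasting difference between the genotypes. The series asked which genes respond to acute progesterone through its receptor.

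The targeted gene was looked at first. Pgr, which encodes the receptor, was represented by a probe set at 9.94 ± 0.06 (log2, SD, n = 3) in wild type and 8.89 ± 0.29 in null glands at 8 h, 2.08-fold higher in wild type (SE 0.19, adjusted p = 0.012). The call was lost without null pool 2 (adjusted p = 0.056) or wild type pool 1 (adjusted p = 0.061). At 24 h the values were 7.82 ± 0.29 and 7.46 ± 0.35, 1.28-fold apart (adjusted p = 0.45). Another Pgr probe set went the other way and was 3.92-fold higher in null glands at 8 h (adjusted p = 6.0e-05) and 4.28-fold higher at 24 h (adjusted p = 9.0e-05), and the remaining one was too low to be tested. The null allele is not described in the labels and the position of these probes relative to it is not known here, so Pgr signal checks the genotype labels only in part.

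**Figure D1:**
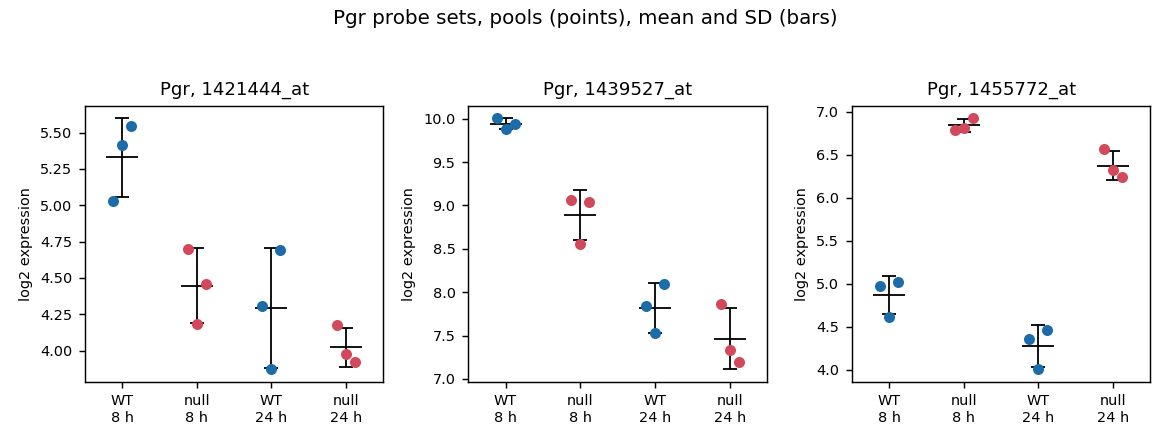
Log2 expression of the 3 Pgr probe sets in each of the 4 groups (x axis: genotype and hours of progesterone; points are pools, bars the mean and SD of 3 pools). The probe set in the centre panel is higher in wild type at 8 h, whereas the one in the right panel is higher in null glands at both times and the one in the left panel was not tested.

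At 8 h of progesterone, wild type glands had higher Cited1, a transcriptional co-regulator of estrogen receptor signalling (9.35-fold, SE 0.34, n = 3 per group, adjusted p = 0.00051). Among genes higher in wild type the largest differences were in Cntnap2 (18.2-fold, SE 0.44), Rarres1 (13.1-fold, SE 0.47), Cited1, Rbm46 (7.43-fold, SE 0.31) and the angiotensin receptor gene Agtr2 (6.25-fold, SE 0.41). Fcgbp (6.23-fold), the aldehyde dehydrogenase gene Aldh3a1 (6.10-fold), Pcp4 (4.58-fold), Gm266 (4.34-fold) and Ifnz (4.32-fold) followed. Null glands had higher Tph1, the enzyme that starts serotonin synthesis (14.2-fold, SE 0.38), Aoc1, a diamine oxidase (10.5-fold, SE 0.36), and Ido1, which degrades tryptophan (7.92-fold, SE 0.18). The antibody genes Igha (7.49-fold) and Jchain (7.12-fold) and Nat1 (6.79-fold), Arg1 (6.74-fold), Padi4 (6.06-fold), 2210407C18Rik (5.94-fold) and the epidermal growth factor family ligand Epgn (5.46-fold) were also higher in null glands.

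Of 16 tested progesterone targets, Cited1 and the secreted ligand gene Wnt4 (1.95-fold, SE 0.19, adjusted p = 0.017) were higher in wild type at 8 h, Wnt5a was lower (1.55-fold, adjusted p = 0.010) and 13 were not called. Adjusted over the list alone, 4 were higher and 2 lower, and the list did not pass (adjusted p = 0.21). Among the uncalled targets, Tnfsf11 lay 2.23-fold (adjusted p = 0.31), Elf5 1.69-fold (adjusted p = 0.085) and Id4 1.10-fold (adjusted p = 0.78) higher in wild type, and Gata3 1.58-fold lower (adjusted p = 0.10). Of 14 estrogen responsive genes, Stc2 (2.65-fold) and Myb (2.08-fold) were higher and Slc7a2 lower (1.85-fold) in wild type, 2 higher and 1 lower when adjusted over the list alone. That list did not pass (adjusted p = 0.56), and its test and mean were above 0 but its median was -0.003 (log2). The call of Wnt4 was lost without wild type pool 1, wild type pool 2, null pool 2 or null pool 3 (adjusted p 0.062 to 0.079). That of Myb was lost without wild type pool 1 (0.068), and that of Slc7a2 without wild type pool 1, wild type pool 2 or null pool 3 (0.051 to 0.065).

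The luminal keratins Krt8 (1.74-fold, adjusted p = 0.0032) and Krt18 (1.31-fold, adjusted p = 0.039) and the junction gene Cldn4 (1.54-fold) were lower in wild type at 8 h, whereas the protease inhibitor gene Spint1 was higher (1.69-fold). These were the 4 called of 18 epithelial keratin and adhesion genes, and adjusted over the list alone 2 were higher and 5 lower (list adjusted p = 0.28). The call of Krt18 was lost without any 1 of the 6 pools (adjusted p 0.074 to 0.18) and after quantile normalization (0.054). Of 10 brown adipocyte markers, Fabp3 (5.04-fold), the uncoupling protein gene Ucp1 (3.91-fold) and Cidea (3.16-fold) were lower in wild type, and adjusted over the list alone 7 were lower. The list passed with the preset correlation (adjusted p = 0.00016) but had adjusted p = 0.90 with an estimated correlation. Fabp3 lost its call without any 1 pool but wild type pool 1 (0.081 to 0.16), Ucp1 without null pool 1, null pool 2 or wild type pool 3 (0.059 to 0.085), and Cidea without those 3 or wild type pool 2 (0.056 to 0.078).

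Endothelial markers were lower in wild type at 8 h by the list test (adjusted p = 0.00040; adjusted p = 0.90 with an estimated correlation) and by a median of 0.23 (log2), yet the 1 called of 16, the von Willebrand factor gene Vwf, was higher (1.78-fold), as when adjusted over the list alone. Skeletal muscle markers were higher in wild type by a median of 1.76 (log2), though limma called 0 of 20, with 3 at an unadjusted p under 0.05 (list adjusted p = 6.8e-05; adjusted p = 0.90 with an estimated correlation). Their mean in single pools ranged from 1.48 to -3.25 relative to the gene means, and the list call was lost without null pool 2 (0.058). Of 23709 probe sets, 729 were called at 8 h, which included the representing probe sets of 361 genes. Of the 729, 364 were higher in wild type and 365 higher in null glands. The count fell to 320 without wild type 8 h pool 1, 367 without wild type pool 2, 366 without null pool 2 and 433 without null pool 3.

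**Figure D2:**
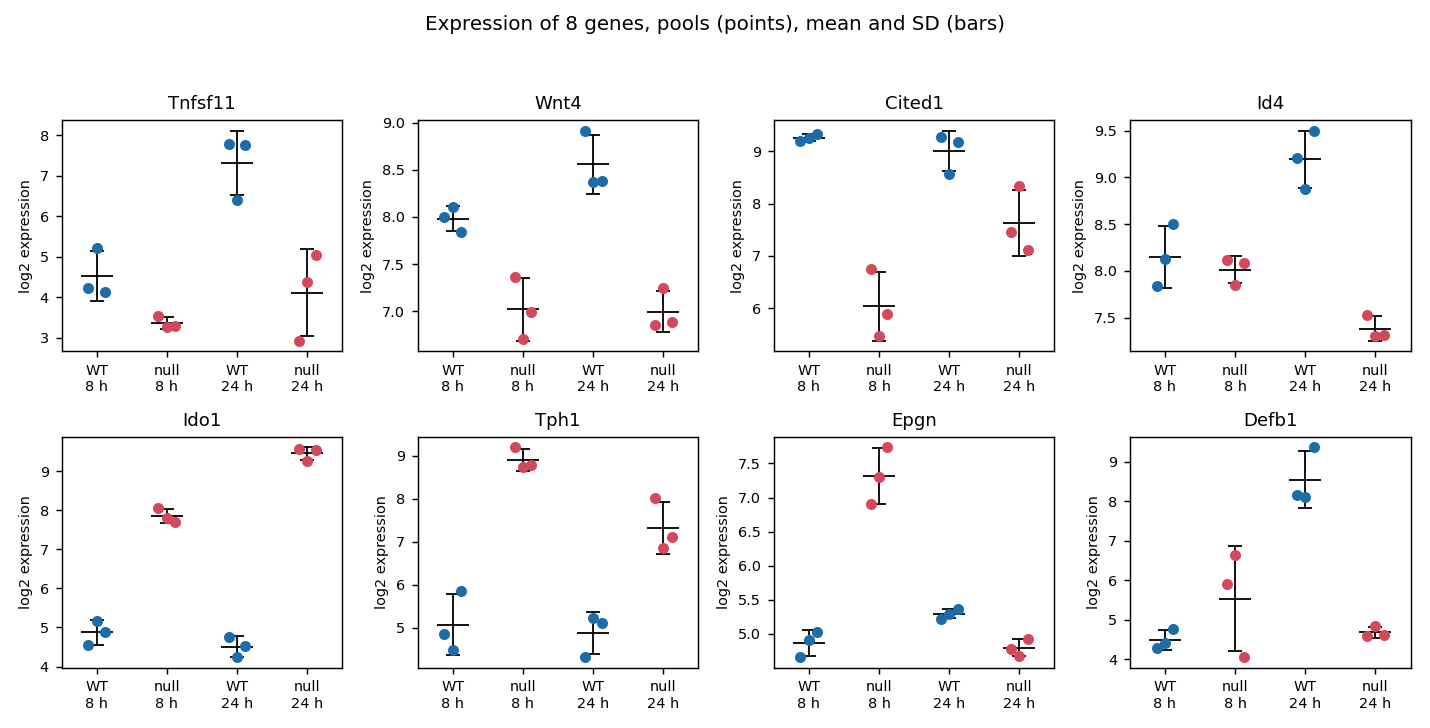
Log2 expression of 8 genes in each group (x axis: genotype and hours of progesterone; points are pools, bars the mean and SD of 3 pools). Ido1 and Tph1 are higher in null glands at both times, and Defb1 is higher in wild type at 24 h.

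At 24 h of progesterone, wild type glands had higher Tnfsf11, which encodes RANKL (9.20-fold, SE 0.52, n = 3 per group, adjusted p = 0.011), Wnt4 (2.96-fold, SE 0.19, adjusted p = 0.0017), Id4 (3.50-fold, SE 0.18, adjusted p = 0.00049), the WNT co-agonist Rspo1 (2.61-fold, SE 0.16, adjusted p = 0.0017) and the cell cycle gene Ccnd1 (2.04-fold, SE 0.14, adjusted p = 0.0041). Among genes higher in wild type the largest difference was in the antimicrobial peptide gene Defb1 (14.5-fold, SE 0.53), followed by Aldh3a1 (9.49-fold), Tnfsf11, Fcgbp (7.18-fold), Cntnap2 (6.40-fold), Gm266 (4.75-fold), Wfdc12 (4.55-fold), the fibrinogen gene Fgg (4.53-fold), the surfactant protein gene Sftpd (4.42-fold) and Prom2 (3.72-fold). Null glands had higher Ido1 (30.9-fold, SE 0.18, adjusted p = 1.6e-07), Dmbt1 (17.7-fold, SE 0.38), Tph1 (5.44-fold), Aoc1 (4.67-fold), 2210407C18Rik (4.38-fold), the iodide transporter gene Slc5a5 (4.38-fold), Igha (4.10-fold), Capsl (3.39-fold), Ly6d (3.16-fold) and Cxcl15 (2.66-fold). The calls of Id4, Wnt4, Rspo1, Ccnd1, Defb1 and Ido1 were kept whichever pool was left out. Those lost were Tnfsf11 without wild type pool 1 (adjusted p = 0.064) or 3 (0.070), Cntnap2 without null pool 2 (0.053) or wild type pool 3 (0.079), and Fgg without wild type pool 3 (0.079). Wfdc12 was lost without null pool 2 (0.056) or 3 (0.053), and Aoc1 without wild type pool 1 (0.051) or 3 (0.054).

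Of 16 progesterone targets, 5 were higher in wild type at 24 h, Wnt5a was lower (1.49-fold), and adjusted over the list alone 8 were higher and 2 lower. The list passed with the preset correlation (adjusted p = 0.00099) but had adjusted p = 0.30 with an estimated correlation. Of the 10 uncalled targets, Cited1 (2.59-fold, adjusted p = 0.094), Greb1 (1.85-fold, adjusted p = 0.23) and Elf5 (1.46-fold, adjusted p = 0.28) lay higher in wild type and Gata3 lower (1.32-fold, adjusted p = 0.38). The call of Wnt5a was lost without any 1 of the 6 pools but wild type pool 2 (0.072 to 0.14). Of 14 estrogen responsive genes, Tfap2c (2.77-fold) and Stc2 (2.45-fold) were higher and Slc7a2 lower (1.85-fold), and adjusted over the list alone 4 were higher and 1 lower (list adjusted p = 0.13). Stc2 (0.081 to 0.10) and Slc7a2 (0.066 to 0.088) lost their calls without null pool 1, null pool 3, wild type pool 1 or wild type pool 3.

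Of 18 epithelial keratin and adhesion genes, 6 were higher and 0 lower in wild type at 24 h, among them Cldn7 (2.28-fold), the splicing regulator gene Esrp1 (2.09-fold), Cldn3 (1.99-fold) and E-cadherin, Cdh1 (1.81-fold), and adjusted over the list alone 14 were higher (list adjusted p = 6.1e-13; adjusted p = 0.30 with an estimated correlation). Krt8 lay 1.14-fold lower (adjusted p = 0.52) and Krt18 1.14-fold higher (adjusted p = 0.41), and neither was called. Of 15 luminal progenitor and alveolar markers 3 were higher, including Rspo1 and Lcn2 (1.93-fold), and adjusted over the list alone 10 were higher (list adjusted p = 1.6e-07; adjusted p = 0.30 with an estimated correlation). Of 17 basal and myoepithelial markers Trp63 was higher (2.65-fold), and adjusted over the list alone 5 were higher (list adjusted p = 0.00052; adjusted p = 0.52 with an estimated correlation). Lcn2 lost its call without null pool 2, null pool 3 or wild type pool 3 (0.056 to 0.091), and Trp63 without those 3 or wild type pool 1 (0.10 to 0.15). The mean of the epithelial list in wild type pool 2 was -0.04, against 0.41 and 0.52 in pools 1 and 3 and -0.54 to -0.31 in null pools.

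The receptor gene Erbb3 (1.91-fold) was the 1 called of 12 ErbB ligands and receptors at 24 h, also when adjusted over the list alone (list adjusted p = 0.0078, lost without null pool 3 at 0.069; adjusted p = 0.30 with an estimated correlation). Skeletal muscle markers were again higher in wild type by a median of 1.67 (log2), with limma calling 0 of 20 and 3 at an unadjusted p under 0.05 (list adjusted p = 0.00074; adjusted p = 0.65 with an estimated correlation). That list call was lost without wild type pool 1 (0.25). The 262 probe sets called at 24 h included the representing probe sets of 156 genes. Most of the 262 were higher in wild type (207, against 55 higher in null glands). Without wild type pool 2, 704 were called, against 126 without pool 3, 149 without pool 1 and 155 without null pool 2.

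**Figure D3:**
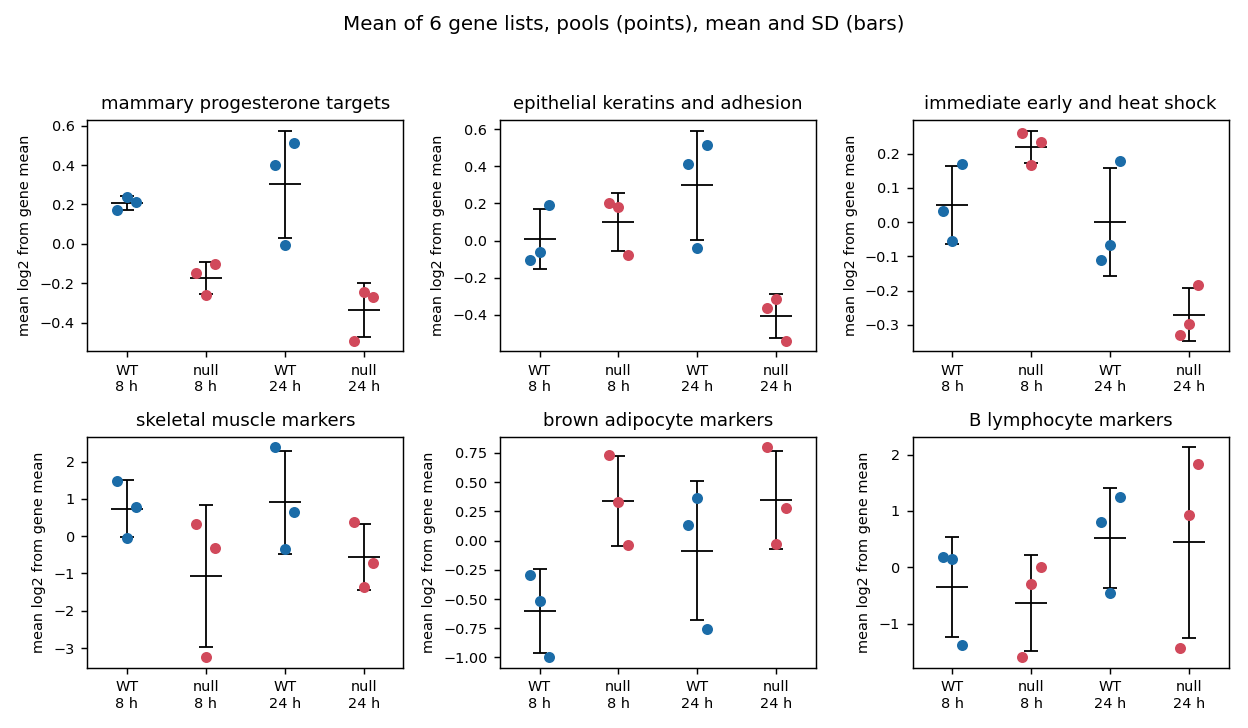
Mean log2 expression of 6 gene lists, each gene taken relative to its mean over the 12 arrays (x axis: genotype and hours of progesterone; points are pools, bars the mean and SD of 3 pools). For progesterone targets, wild type pools lie between 0.17 and 0.24 at 8 h and between -0.01 and 0.51 at 24 h, and null pools between -0.26 and -0.10 and between -0.49 and -0.25.

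Genotype differences were then compared between the times. Of the genes tested, 39 were higher in wild type at both times (2.00 expected by chance; one-sided Fisher's exact p = 2.2e-40) and 21 higher in null glands at both (0.42 expected by chance; p = 5.4e-33), and limma called 0 in opposite directions. Aldh3a1, Fcgbp, Cntnap2, Gm266, Wnt4 and Stc2 were among the first, and Ido1, Tph1, Aoc1, Igha, Slc5a5, Ly6d and Cxcl15 among the second. Genes are not independent replicates, and both comparisons shared 1 estimate of the spread. The Fisher p-values and the numbers expected by chance thus do not measure the spread between pools. Across 12004 genes the differences at 8 h and 24 h correlated with r = 0.51 (Spearman's rho 0.48).

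The genotype difference (wild type minus null) changed between 8 h and 24 h for 34 probe sets, which included the representing probe sets of 16 genes. It became more positive for Defb1 (30.0-fold, SE 0.75, n = 3 per group, adjusted p = 0.037), Arg1 (13.0-fold, SE 0.49), Epgn (7.71-fold, SE 0.26, adjusted p = 0.0020), Padi4 (7.55-fold, SE 0.34), Padi2 (3.35-fold, SE 0.22), Id4 (3.18-fold, SE 0.25) and Cldn4 (1.85-fold, SE 0.14). It became more negative for the milk fat globule gene Btn1a1 (5.63-fold, SE 0.41), Tmprss2 (3.99-fold, SE 0.27), Ido1 (3.90-fold, SE 0.25) and Igsf21 (2.00-fold, SE 0.16). Epgn, Padi4 and Padi2 were higher in null glands at 8 h, by 5.46-fold, 6.06-fold and 4.14-fold, and were not called at 24 h (adjusted p = 0.27, 0.61 and 0.41). Of these 11 calls, those of Epgn, Padi4, Padi2 and Ido1 were kept whichever pool was left out. Arg1 was lost without null 24 h pool 3 (adjusted p = 0.0505) and Tmprss2 without null 8 h pool 2 (0.056) or 3 (0.066).

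The other 5 interaction calls were each lost in 10 of the 12 fits that left out a pool. Defb1 was kept without null 8 h pool 3 or wild type 24 h pool 2 (adjusted p 0.056 to 0.12 in the others), and Id4 without wild type 8 h pool 3 or wild type 24 h pool 2 (0.053 to 0.12). Cldn4 was kept without wild type 8 h pool 2 or null 24 h pool 2 (0.056 to 0.14), Btn1a1 without null 8 h pool 1 or null 24 h pool 1 (0.0505 to 0.16), and Igsf21 without wild type 24 h pool 3 or null 24 h pool 3 (0.073 to 0.15). Btn1a1, Igsf21 and Cldn4 also lost their calls after quantile normalization (0.058, 0.075 and 0.094). The epithelial list passed (adjusted p = 1.7e-20; adjusted p = 0.16 with an estimated correlation), with 1 of 18 members called and 12 more positive when adjusted over the list alone. The change did not pass the test for Tnfsf11 (4.12-fold, adjusted p = 0.63), Cited1 (3.61-fold, adjusted p = 0.30) or Wnt4 (1.52-fold, adjusted p = 0.86). The count fell to 12 without wild type 8 h pool 1, 19 without pool 2, 18 and 17 without null 8 h pools 2 and 3, and 22 and 17 without null 24 h pools 1 and 3.

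Between 8 h and 24 h in wild type glands, Defb1 (16.7-fold, SE 0.53, n = 3 per group), Jchain (8.65-fold, SE 0.52), Tnfsf11 (6.93-fold, SE 0.52, adjusted p = 0.014), Arg1 (4.33-fold, SE 0.35) and Sftpd (4.15-fold, SE 0.16) rose most. Btn1a1 (5.44-fold, SE 0.29), the collagen-modifying enzyme gene Plod2 (5.01-fold, SE 0.29), Pgr (4.36-fold, SE 0.19), Tmem158 (4.35-fold, SE 0.17) and Akr1c14 (4.30-fold, SE 0.22), whose enzyme reduces steroids, fell most. The other tested Pgr probe set lay 1.51-fold lower at 24 h (adjusted p = 0.052). Of 16 progesterone targets 3 rose, Tnfsf11, Rspo1 (2.16-fold) and Id4 (2.06-fold), and 2 fell, including Greb1 (3.46-fold). Adjusted over the list alone 5 rose and 3 fell, the list did not pass (adjusted p = 0.88), and its test and mean were above 0 but its median was -0.11 (log2). Without wild type 8 h pool 1, Tnfsf11 (0.071) and Id4 (0.0501) lost their calls.

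Of 14 estrogen responsive genes 5 fell in wild type glands, including Greb1 and Myb (2.07-fold), and adjusted over the list alone 6 fell and 1 rose (list adjusted p = 0.025; adjusted p = 0.66 with an estimated correlation). Of 26 G1/S genes 2 rose, Mcm7 (1.51-fold) and Lig1 (1.40-fold), and 4 when adjusted over the list alone (list adjusted p = 7.1e-05; adjusted p = 0.68 with an estimated correlation). Of 19 G2/M genes Anln rose (1.47-fold), and 2 when adjusted over the list alone (list adjusted p = 0.00011; adjusted p = 0.68 with an estimated correlation). Of 15 clock genes Nr1d1 rose (1.48-fold) and 3 fell, including Nfil3 (1.49-fold) and Tef (1.41-fold), and adjusted over the list alone 1 rose and 6 fell (list adjusted p = 0.016; adjusted p = 0.66 with an estimated correlation). The oxytocin receptor gene Oxtr fell 2.66-fold. Calls were lost without wild type 8 h pool 1 for Myb (0.073), Mcm7 (0.071), Lig1 (0.13), Anln (0.16), Nr1d1 (0.078), Nfil3 (0.12) and Tef (0.098). They were also lost without 8 h pool 2 for Mcm7 (0.054), Lig1 (0.12), Anln (0.14), Nfil3 (0.072) and Tef (0.070), and without 8 h pool 3 for Lig1 (0.099), Nr1d1 (0.0501) and Nfil3 (0.098). The same held without 24 h pool 1 for Lig1 (0.12), without 24 h pool 2 for Anln (0.11), Nr1d1 (0.052) and Nfil3 (0.079), and without 24 h pool 3 for Mcm7 (0.052), Lig1 (0.11), Anln (0.11) and Nfil3 (0.060). The estrogen list lost its call without 24 h pool 1 (0.070) or 8 h pool 3 (0.081). In all, 1238 probe sets were called, of which 363 rose and 875 fell. The count was 239 without wild type 8 h pool 1, 486 without pool 2, 799 without pool 3, 702 without 24 h pool 2 and 699 without 24 h pool 3. The share that rose was 29.3%, against 37.9% after quantile normalization.

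Of 18 epithelial keratin and adhesion genes 3 rose in wild type glands, Cldn3 (1.42-fold), Krt8 (1.39-fold) and Cldn4 (1.33-fold), and adjusted over the list alone 4 rose and 1 fell (list adjusted p = 0.00083; adjusted p = 0.68 with an estimated correlation). These calls were lost without any 1 of the 6 pools but 24 h pool 2 for Cldn3 (0.051 to 0.14) and Krt8 (0.080 to 0.12). Cldn4 lost its call without any but 8 h pool 2 (0.070 to 0.17). Lymphocyte markers lay higher at 24 h in wild type glands, by a median of 0.74 (log2) for T cells and 0.88 for B cells (list adjusted p = 0.023 and 0.017; adjusted p = 0.68 with an estimated correlation for both). For these lists limma called 0 of 15 and 0 of 16, with 0 and 1 at an unadjusted p under 0.05. The T cell list lost its call without wild type 24 h pool 1 (0.17), 24 h pool 3 (0.088) or 8 h pool 3 (0.47) and after quantile normalization (0.065). The B cell list lost it without 24 h pool 1 (0.11), 24 h pool 3 (0.088) or 8 h pool 3 (0.31). In 24 h pools 1, 2 and 3 the mean was 0.60, -0.59 and 0.81 for the T cell list and 0.80, -0.46 and 1.24 for the B cell list. It was 0.28, 0.02 and 0.40 for the G2/M genes and 0.33, 0.09 and 0.31 for the G1/S genes, so pool 2 was lowest for all 4 lists. At 8 h the lists did not rank the wild type pools alike. There pool 3 was lowest for the T cell (-1.20) and B cell (-1.37) lists but highest for the G2/M (-0.11) and G1/S (-0.04) genes. In null glands at 8 h, pool 1 was lowest for all 4 lists.

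In null glands over the same interval, Dmbt1 (7.34-fold, SE 0.38, n = 3 per group), Cited1 (3.03-fold, SE 0.34), Ido1 (3.03-fold, SE 0.18), Pacc1 (2.58-fold, SE 0.14) and Crym (2.51-fold, SE 0.27) rose most. Mmd2 (12.4-fold, SE 0.30), the estrogen responsive gene Greb1 (6.59-fold, SE 0.30), Padi4 (5.92-fold, SE 0.24), Epgn (5.72-fold, SE 0.19) and Wfdc2 (4.53-fold, SE 0.08) fell most. Cited1 lost its call without null 24 h pool 2, 8 h pool 2 or 8 h pool 3 (adjusted p 0.097 to 0.10), and Crym without any 1 of the 6 pools but 24 h pool 1 (0.052 to 0.075). Of 22 immediate early and heat shock genes 8 fell, among them Egr1 (2.89-fold), Jun (1.65-fold) and Junb (1.57-fold), and limma called 0 as rising. Adjusted over the list alone 12 fell, of 13 at an unadjusted p under 0.05 (list adjusted p = 1.8e-06; adjusted p = 0.21 with an estimated correlation). Egr1 lost its call without null 24 h pool 2 (0.062), and Junb without that pool or 8 h pool 3 (0.072 each).

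Of 14 estrogen responsive genes 3 fell in null glands, Greb1, Stc2 (2.07-fold) and Myb (1.76-fold), and adjusted over the list alone 9 fell and 1 rose (list adjusted p = 0.0020; adjusted p = 0.21 with an estimated correlation). Stc2 lost its call without any 1 of the 6 pools but null 24 h pool 2 (0.069 to 0.12), and Myb without any but null 8 h pool 2 (0.051 to 0.15). The cell cycle lists passed as well, higher at 24 h by a median of 0.15 (log2) for G1/S genes and 0.38 for G2/M genes (list adjusted p = 0.0018 and 0.00064; adjusted p = 0.68 with an estimated correlation for both). For these lists limma called 0 of 26 and 0 of 19, with 4 and 6 at an unadjusted p under 0.05. The G1/S list lost its call without null 24 h pool 3 (0.14), and the G2/M list without that pool (0.064) or 8 h pool 1 (0.052). Between genotypes at 24 h the G1/S list passed too, higher in wild type (list adjusted p = 0.0018). That call was lost without null 24 h pool 1 (0.078) and with an estimated correlation. The clock list did not pass in null glands (adjusted p = 0.82), though limma called 2 of its members there, Nfil3 and Nr1d1. The call of Nfil3 was kept whichever pool was left out, and that of Nr1d1 was lost in 5 of these fits. Changes in clock genes were thus not confined to wild type glands. The clock list passed in the interaction test of the difference between genotypes (adjusted p = 0.018; adjusted p = 0.26 with an estimated correlation), with limma calling 0 of 15 and 5 at an unadjusted p under 0.05. That call was lost without null 24 h pool 2 (0.071), null 8 h pool 1 (0.052) or wild type 24 h pool 3 (0.080).

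Of 18 epithelial keratin and adhesion genes 7 fell in null glands, among them Krt7 (1.75-fold) and Cldn7 (1.72-fold), and 12 when adjusted over the list alone (list adjusted p = 1.8e-06; adjusted p = 0.68 with an estimated correlation). Of 15 luminal progenitor and alveolar markers 5 fell, including Kit (1.80-fold) and Cebpb (1.61-fold), and 8 when adjusted over the list alone (list adjusted p = 4.4e-05; adjusted p = 0.45 with an estimated correlation). Of 16 endothelial markers 3 fell, including Tie1 (1.62-fold) and Pecam1 (1.42-fold), and 4 when adjusted over the list alone (list adjusted p = 0.00049; adjusted p = 0.68 with an estimated correlation). Lymphocyte markers lay higher at 24 h in null glands too, by a median of 1.02 (log2) for T cells and 1.07 for B cells (list adjusted p = 0.00018 and 0.00054; adjusted p = 0.68 with an estimated correlation for both). For these lists limma called 0 of 15 and 0 of 16, with 4 and 1 at an unadjusted p under 0.05. The B cell list had a mean of -1.43, 0.93 and 1.83 in the 24 h pools and lost its call without pool 3 (0.097). In the same pools 1, 2 and 3 the mean was -0.98, 0.81 and 1.71 for the T cell list, -0.21, 0.10 and 0.45 for the G2/M genes and -0.29, 0.00 and 0.23 for the G1/S genes, so the pools ranked alike for all 4 lists. Cldn7 lost its call without 24 h pool 3 (0.051) or 8 h pool 3 (0.067). For time in wild type the luminal progenitor (adjusted p = 0.26), immediate early (0.10) and endothelial (0.86) lists did not pass, but limma called members of each there too. Among them were Cebpb and Tie1, named above for null glands, and the immediate early genes Jund and Nr4a2. In wild type the call of Cebpb was kept whichever pool was left out, and that of Tie1 was lost without any 1 of the 6 pools. In the interaction test these 3 lists passed (adjusted p = 0.00019, 0.00064 and 1.9e-05; adjusted p = 0.29, 0.27 and 0.29 with an estimated correlation), with limma calling 0 members of each and 7, 7 and 3 at an unadjusted p under 0.05.

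Of 1044 probe sets called in null glands, 193 rose and 851 fell. The share that rose was 18.5%, against 30.2% after quantile normalization and 29.1% after centring each array. With the replicate block in the fit the count was 1667. Of 17 basal and myoepithelial markers 1 fell, and 2 when adjusted over the list alone (list adjusted p = 0.027, or 0.053 with the replicate block; adjusted p = 0.68 with an estimated correlation), a list call also lost without null 8 h pool 2 (0.10) or 24 h pool 3 (0.19). With the block 2 more lists passed. The unfolded protein response lay lower at 24 h (0.019, against 0.054 without the block; adjusted p = 0.69 with an estimated correlation), and the skeletal muscle markers lay higher (0.0043, against 0.082; adjusted p = 0.81 with an estimated correlation). For these lists limma called 0 of 20 each, with 8 and 0 at an unadjusted p under 0.05. The count was 232 without null 8 h pool 3, 413 without null 8 h pool 2, 315 without null 24 h pool 2 and 532 without null 24 h pool 3. Of the genes tested, 30 rose in both genotypes (1.28 expected by chance) and 202 fell in both (17.6 expected by chance), among them Pgr, Greb1, Oxtr, Akr1c14, Plod2 and Wfdc2. The other tested Pgr probe set was called in neither genotype (in null glands 1.38-fold lower at 24 h, adjusted p = 0.12). Across genes, which are not independent replicates, the changes in wild type and null glands correlated with r = 0.48 (Spearman's rho 0.59).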

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

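The window test for genes called at both times, the test on probe sets of 1 gene, the count of neighbouring genes, the keratin test, the permutation of residuals and the splits of the paired null arrays were chosen only after the result was seen. The genotype difference changed between 8 h and 24 h, by the interaction test, for 16 genes, of which 11 were named for that test. Sftpd, named for other comparisons, was among the 16 as well (log2 change 1.73, adjusted p = 0.014). The 11 follow. On the log2 scale the change was 4.91 for Defb1, 3.70 for Arg1, 2.95 for Epgn, 2.92 for Padi4, 1.74 for Padi2, 1.67 for Id4 and 0.89 for Cldn4. It was -2.49 for Btn1a1, -2.00 for Tmprss2, -1.96 for Ido1 and -0.997 for Igsf21. Of these 11, 4 (Epgn, Padi4, Padi2 and Ido1) kept their call whichever pool was left out.

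For the interaction, 34 probe sets were called, and 6 of 100 splits of the arrays, the real one included, called as many (highest other 1571). Of the 5 other splits, 4 relabelled more arrays at 24 h than at 8 h, which turns the contrast toward the mean genotype difference, so this count cannot tell whether chance is excluded. The remaining one relabelled 2 arrays at each time and called 79. When the residuals of a fit with genotype and time but no interaction were permuted over the arrays, 2 of 100 permutations, the real order included, called as many and 98 called 0. That share lay under 0.05, as predicted if chance was not the cause. The permutation takes the arrays as exchangeable, however, whereas same-numbered null arrays correlated in their deviations (r from 0.26 to 0.52). It therefore cannot exclude chance for the count of 34. The other permutation called 1262, for a reason that was not tested, and the test does not speak for single genes.

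The comparisons of 3 arrays with 3 allow 10 splits, too few for a share under 0.05, and in each 1 split, the real one, called as many. The real and highest other counts were 729 and 3 for genotype at 8 h, 262 and 0 for genotype at 24 h, 1238 and 0 for time in wild type, and 1044 and 0 for time in null glands. Of the null splits, 4 part every same-numbered pair, and of these 1, the real one, called as many (highest other 0).

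Genes called between genotypes may include genes in DNA flanking the targeted Pgr allele that came from another strain. For the 24 h calls, 5 of 107 tested genes within 20 Mb of Pgr were called (Cfap300, Casp4, Qtrt1, Pdgfd and Ap1m2, named after their values were seen), against 150 of 11858 elsewhere, a higher share (odds ratio 3.83, 95% interval 1.20 to 9.42, two-sided Fisher's exact p = 0.013, adjusted over the 2 planned tests 0.025). For the 8 h calls it was 4 of 107 against 356 of 11858 (odds ratio 1.25, 95% interval 0.33 to 3.34, Fisher's exact p = 0.57), and for genes called the same way at both times 2 of 107 against 58 of 11858 (odds ratio 3.87, 95% interval 0.45 to 15.0, Fisher's exact p = 0.10), too few to decide. The both-times odds ratio was 9.97 within 10 Mb (Fisher's exact p = 0.020) and 1.89 within 40 Mb (p = 0.29). The 24 h test thus met the prediction for a difference in flanking DNA. Such DNA would be present at 8 h too, where of those 5 genes Cfap300 and Pdgfd were called the same way. At 8 h Casp4 (log2 0.59, adjusted p = 0.18), Qtrt1 (0.31, adjusted p = 0.23) and Ap1m2 (-0.07, adjusted p = 0.78) were not called. An effect of the receptor on the 5 genes was not tested. Outside the window lie 150 other genes called at 24 h, of those with a known position.

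Some genotype calls at 8 h rested on 1 probe set of a gene. Of 98 called probe sets with at least a 2-fold change and another tested probe set of the same gene, Pgr aside, 24 had no other with at least 0.25 of the change, against 6 of 57 for time in null glands (odds ratio 2.74, 95% interval 0.998 to 8.79, two-sided Fisher's exact p = 0.037) but 16 of 82 for time in wild type (odds ratio 1.34, 95% interval 0.62 to 2.94, p = 0.47). With at least a 4-fold change it was 9 of 26, against 0 of 5 (Fisher's exact p = 0.29) and 2 of 12 (p = 0.44). At 24 h, where a difference in strain background would act too, it was 9 of 64 at 2-fold, and neither test passed (against time in wild type odds ratio 0.68, 95% interval 0.24 to 1.78, Fisher's exact p = 0.51; against time in null glands odds ratio 1.39, 95% interval 0.41 to 5.09, Fisher's exact p = 0.59). A candidate explanation of the 8 h calls is such a difference between the mice of the groups, which the labels give as BALB/c throughout, but only 1 of the 4 tests at 8 h passed, the 24 h intervals leave an excess possible without showing one, and transcript ends that depend on the receptor were not tested, so both stay open.

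Neighbouring gene pairs called at 8 h numbered 20, against 10.9 in random draws (95% of draws 5 to 17.0), and at 24 h 10, against 2.0 (0 to 5), with 48 against 33.3 (23 to 44) for time in wild type and 34 against 24.9 (16 to 35) for time in null glands.

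The list of 18 epithelial keratin and adhesion genes passed at 24 h with the preset correlation but not with an estimated one. Its median lay 0.65 (log2) higher in wild type. A uniformly lower share of epithelium in the null pools would lower the abundant keratins by about as much. The wild type minus null difference was -0.19 for Krt8 (upper 95% bound 0.06) and 0.18 for Krt18 (upper 95% bound 0.38), both below that median, and Krt19 lay at -0.26 (upper 95% bound 0.12). Krt7 was higher in wild type (0.46, 95% interval 0.25 to 0.68, adjusted p = 0.046, a call lost without any 1 of the 6 pools but wild type pool 2, at 0.058 to 0.18), and Krt14 lay higher (1.72, 95% interval 0.75 to 2.69, adjusted p = 0.10). The 5 keratins thus did not move alike, and Krt8 and Krt18 did not meet the prediction for a uniform loss. That prediction takes keratin per epithelial cell to be equal in both genotypes. At 8 h, however, Krt8 and Krt18 were called lower in wild type, so the test cannot exclude a uniform loss. Changes in part of the epithelium, and an effect of the receptor on these genes, were not tested and stay open.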

How the results depend on the processing

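The test without the 2 least correlated 24 h arrays and the block within the null arrays alone were chosen after seeing the data, and all other alternatives before. Counts of called probe sets moved by over 1.5 times under these settings. Above the 70th percentile, genotype at 24 h gave 164 and the interaction 22. With array weights, genotype at 8 h gave 4017, genotype at 24 h 685, the interaction 169 and time in null glands 5775. With only the 6 arrays of a comparison, genotype at 24 h gave 71, time in wild type 500 and time in null glands 348. With 1 probe set per gene, where fewer features were tested, the counts were 339, 165, 10, 649 and 572 in the order genotype at 8 h, genotype at 24 h, interaction, time in wild type and time in null glands. In the same order, the main fit called 361, 156, 16, 634 and 548 representing probe sets. Against these like counts only the interaction moved by over 1.5 times. With a 1.5-fold threshold, time in wild type gave 502 and time in null glands 443. Without the 2 least correlated arrays, genotype at 24 h gave 466 and time in wild type 784. Apart from fewer features, fewer arrays and the added fold threshold, the cause was not tested.

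With the replicate block, time in null glands gave 1667, and 1000 with the replicate block within the null arrays alone. The first changed 3 list calls, given in the report, and no other list or named gene call of this comparison. With the second, Wnt5a (0.056), Egr2 (0.051) and Kdr (0.061) were not called for time in null, and the unfolded protein response (0.042) and skeletal muscle markers (0.035) passed. In the other comparisons the labels give the samples only a shared number. There 1 of 3 pairs had a correlation of deviations over 0.1 for genotype at 8 h (-0.03 to 0.13), genotype at 24 h (-0.04 to 0.43) and time in wild type (-0.01 to 0.45). Of all arrays, 9 of 12 correlated best with an array of their own number, a hint from the data and not the design. In every group the mean of the skeletal muscle markers ranked pool 1 above pool 3, and pool 3 above the remaining pool. That list was picked after its values were seen, and the T cell list did not rank the pools alike. A factor shared by number outside the null arrays was thus not excluded. The block gave 1042 for genotype at 8 h, 482 for genotype at 24 h, 28 for the interaction and 1815 for time in wild type. Over all comparisons 185 named calls were counted with the block, against 190 in the main fit.

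Leaving out 1 array at a time gave 320 to 575 for genotype at 8 h, 126 to 704 for genotype at 24 h, 12 to 45 for the interaction, 239 to 866 for time in wild type and 232 to 1008 for time in null glands. Named calls kept in every such fit numbered 31 of 43, 25 of 41, 4 of 11, 17 of 51 and 24 of 44.

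Of 54 list calls, 0 held with an estimated correlation. The robust prior and the fold threshold were not run for lists. Genes called the same way at both times numbered 111 at an adjusted p below 0.10, against 60. Over all alternatives, named genes lost a call in 556 cases, gained one in 13 and, uncalled, changed sign in 10, and lists did so in 169, 152 and 140. No named gene reversed. Lists reversed in 3 cases, each without 1 array, and the ranges given are over the fits that left out 1 array. These were macrophage markers in the interaction without null 8 h pool 1 (range -0.319 to 0.0251), skeletal muscle markers in the interaction without null 8 h pool 2 (-1.09 to 0.734) and B lymphocyte markers in genotype at 24 h without null 24 h pool 1 (-0.856 to 0.778). Within 10 Mb and 40 Mb of Pgr, the odds ratio was 5.81 and 2.64 at 24 h and 2.43 and 1.09 at 8 h. Signal over background was not used here, so low probe sets are limited by the filter alone.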

Other observations

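No test in this part was chosen only after the result was seen. The list of chemokine and cytokine genes passed in no comparison (adjusted p from 0.12 for time in null to 0.82 for genotype at 8 h). Cxcl15 was 4.37-fold lower in wild type at 8 h (SE 0.21, n = 3 per group), and fell over time in both genotypes, by 2.68-fold in wild type and 4.39-fold in null glands. The cytokine gene Lif was 1.56-fold higher in wild type at 8 h, a call lost without wild type pool 1 (adjusted p = 0.052), and fell over time by 1.98-fold in wild type and 1.63-fold in null glands. In null glands 5 of 26 members fell, and adjusted over the list alone 7 fell and 1 rose (list adjusted p = 0.12, or 0.020 after quantile normalization and 0.043 after centring; adjusted p = 0.68 with an estimated correlation).

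In wild type glands Lyve1 was 2.89-fold and Cd209f 2.58-fold lower at 24 h than at 8 h, the 2 called of 22 myeloid markers, and adjusted over the list alone 4 were lower (list adjusted p = 0.016; adjusted p = 0.68 with an estimated correlation). The list lost its call without wild type 24 h pool 1 (0.10) or 8 h pool 3 (0.17), and Lyve1 without 8 h pool 1 (0.075) or 8 h pool 3 (0.051). In null glands the list did not pass (adjusted p = 0.42). The interaction test of the difference between genotypes passed for the list (adjusted p = 0.030; adjusted p = 0.88 with an estimated correlation), with limma calling 0 of 22 and 1 at an unadjusted p under 0.05. It was lost without wild type 8 h pool 3 (0.41), wild type 24 h pool 1 (0.29) or null 24 h pool 1 (0.067) or 2 (0.14), and without null 8 h pool 1 the direction turned (0.95).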
